A study of Homo sapiens with 4 samples.

How the data were processed

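Total RNA of H9 human embryonic stem cells was extracted with Trizol 6 days after lentiviral infection at a multiplicity of infection of 10, under 2 µg/mL puromycin for 6 days, per the labels' protocols. Biotinylated cRNA was prepared from 250 ng of total RNA and hybridised to an Affymetrix 3' expression array, which reads mainly the 3' end of transcripts. There were 4 arrays, 2 of cells with a control hairpin (shRFP) and 2 of cells with a hairpin against ATF1 (shATF1), grouped by their titles.

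The submitters' processing notes name MAS5 and RMA, with no versions, roles or order given. The values used are the authors' deposited table of 54675 probe sets on a log2 scale, in which each probe set is centred on its median over the 4 arrays. The centring was read from the values, since the median of every probe set was 0 within 1e-06, and the software that did it is not given in the sources used here. Centring keeps differences between arrays and removes the absolute level. Because the median of 4 values is the mean of the middle pair, these 2 arrays carry mirror-image values, so that a single array's value is not independent of the others, while differences between groups are unaffected. The log base is not stated. It was taken as 2, and the range of the values was read from their numeric steps. Neighbouring single-precision numbers lie farther apart the larger they are, so the step left in a probe set after centring shows the range it was in before. Of all probe sets 98.1% could be placed in a level class (2 to 4, 4 to 8, 8 to 16, and few below), leaving out values under 0.01. Of these, 20.8% lay between 8 and 16, a range that no scanner reaches on a log10 scale. The range speaks against log10 alone and does not exclude a natural log, so base 2 and the fold changes that rest on it are an assumption.

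Gene names came from the platform annotation: 41091 probe sets named 1 gene, 1801 several and 11777 were not listed there, and 62 were controls. Only probe sets with 1 gene were used for genes. Of 19775 genes, 19738 were found by symbol in the gene table of the GRCh38.p14 assembly, and 0 symbols needed an update. Unnamed probe sets were tested apart, with 8 of 11721 higher and 15 lower, and are not reported by name. Probe sets of 1 gene can disagree where they match different transcripts.

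The tests were fixed before the data were examined, and parts of that plan needed absolute levels, which the centred values do not hold. The planned rule of the brightest probe set per gene was replaced by the mean of the probe sets in the gene's highest level class. The planned intensity trend of the variance was left out, and the planned filters on dim probe sets were replaced by level classes. Differences were fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3) with group as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The fit had 2 residual and 3.709 prior degrees of freedom. The 28 gene lists, chosen for stem cells, germ layers, other cell types, signalling, stress and metabolism, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Their members were counted over all genes and adjusted over the list alone. The self-contained test fry was run beside them. Chromosomes were tested with camera, and medians of runs of 25 neighbouring genes were set against 1000 shuffled orders, using the 15319 genes of level class 4 and above.

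Genes named in the text followed a rule: CREB1 and CREM, the 12 largest rises and 12 largest falls among genes past the threshold, up to 4 members of each list past the test or 2 of smallest p where none passed, and a set of lineage factors whatever their values. For the 12 largest rises and falls the rule also asked for a level above the median in the higher group, replaced here by a level of at least 4; list members and lineage factors had no such floor. Other genes were named after their values were seen: COL1A2, COL3A1, CDKN1A and MDM2, the further pluripotency genes PRDM14 and DNMT3B, the ends of the gene run, and the genes of the closing observations.

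The tests were checked on 20 simulated data sets of 19775 genes made for the comparison of shATF1 with shRFP, with 200 genes changed in each. A change of 2 on the log2 scale was called in 97.8% of genes, a change of 1 in 64.9% and a change of 0.5 in 0.909%, and 4.9% of calls were false. A list shifted by 0.4 was called by camera in 20 of 20 data sets with the preset correlation and in 0 with the estimated one, and 11 unshifted lists were called over all data sets. Alternatives were a replicate block, quantile normalization and median centring of the arrays, other rules for probe sets, other thresholds and tests, and leaving out each array. Level classes and a correction for gene length were added after the data were seen. Figures were drawn with matplotlib 3.10.9.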

Results

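Gene expression was measured in H9 cells, an established human embryonic stem cell line, 6 days after infection with lentivirus. The virus carried a short hairpin RNA against ATF1, a transcription factor of the CREB family (shATF1), or a control hairpin against RFP, a fluorescent protein that human cells lack (shRFP). Each group held 2 arrays, and the data cover 54675 probe sets, of which 41091 name exactly 1 gene, giving 19775 genes. The labels give the shATF1 arrays different hairpin clone numbers, so these arrays may stand for 2 hairpins, and each array's own position is described. The labels do not say that the arrays came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. All values are log2 differences, shATF1 minus shRFP, with the moderated standard error (SE).

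The comparison of shATF1 with shRFP asks which transcripts depend on ATF1 in undifferentiated stem cells, early neural genes among them. The level of ATF1 itself is not analysed here, because none of the probe sets used carries its name, and so the lowering of the target was not checked. Of its close relatives, CREB1 differed by 0.13 ± 0.12 (SE, adjusted p = 0.583), with single probe sets from -0.28 to 0.59, and CREM by -0.41 ± 0.19 (SE, adjusted p = 0.277), and neither passed the test. None of the 7 measured genes of the CREB/ATF1 family and its coactivators passed, over all genes or adjusted over the list alone. The histone acetyltransferase CREBBP had the smallest p of that list, with a difference of 0.31 ± 0.10 (SE, adjusted p = 0.16).

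The largest changes were falls. ADGRL4, an adhesion receptor known from endothelial cells, was lower in shATF1 by a log2 difference of -4.31 ± 0.29 (SE, adjusted p = 0.0171). Its lowest array lay between 2 and 4 on the log2 scale before centring, where a transcript cannot be told from background, so its size and rank are uncertain. ANXA1, a phospholipid-binding protein of the annexin family, fell by 3.72 ± 0.67 on the log2 scale, and ADAMTS5, a protease that cleaves the matrix proteoglycan aggrecan, fell by 3.49 ± 0.33. Also among the 12 largest falls, MAP2, a microtubule protein of dendrites, fell by 2.91 ± 0.23, DCC, a netrin receptor, fell by 2.75 ± 0.40, DNER, a neuronal membrane protein with EGF-like repeats, fell by 2.75 ± 0.23, and NAV3, a neuron navigator protein, fell by 3.05 ± 0.40. The others were the gap junction protein GJB2 (-3.36), the membrane-anchored LY6K (-3.26), the collagen COL8A1 (-3.19), the forkhead factor FOXD1 (-2.93) and the TEAD cofactor VGLL3 (-2.72).

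The largest rise by the rule used was that of SP8, a zinc finger transcription factor of limb and forebrain development, which was 7.84-fold higher with a log2 difference of 2.97 ± 0.39 (SE, adjusted p = 0.0294). It rests on 1 of its 2 probe sets, the other giving 0.22, and their mean, 1.60, is below the value of BLACAT1. The long noncoding RNA BLACAT1 rose by 2.27 ± 0.35, and GDF3, a TGF-beta family ligand made by pluripotent cells, rose by 2.02 ± 0.19. NPY1R, a neuropeptide Y receptor, rose by 1.77 ± 0.15. THBS2, a thrombospondin, rose by 1.72 ± 0.26, SFRP2, a secreted regulator of WNT signalling, by 1.59 ± 0.17, and HAS2, a hyaluronan synthase, by 1.55 ± 0.14. The remaining members of the 12 largest rises were TMT1A (1.68), SOX9 (1.62), the potassium channel KCNJ2 (1.61), the dNTP hydrolase SAMHD1 (1.52) and the small GTPase RASL12 (1.51).

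**Figure D1:**
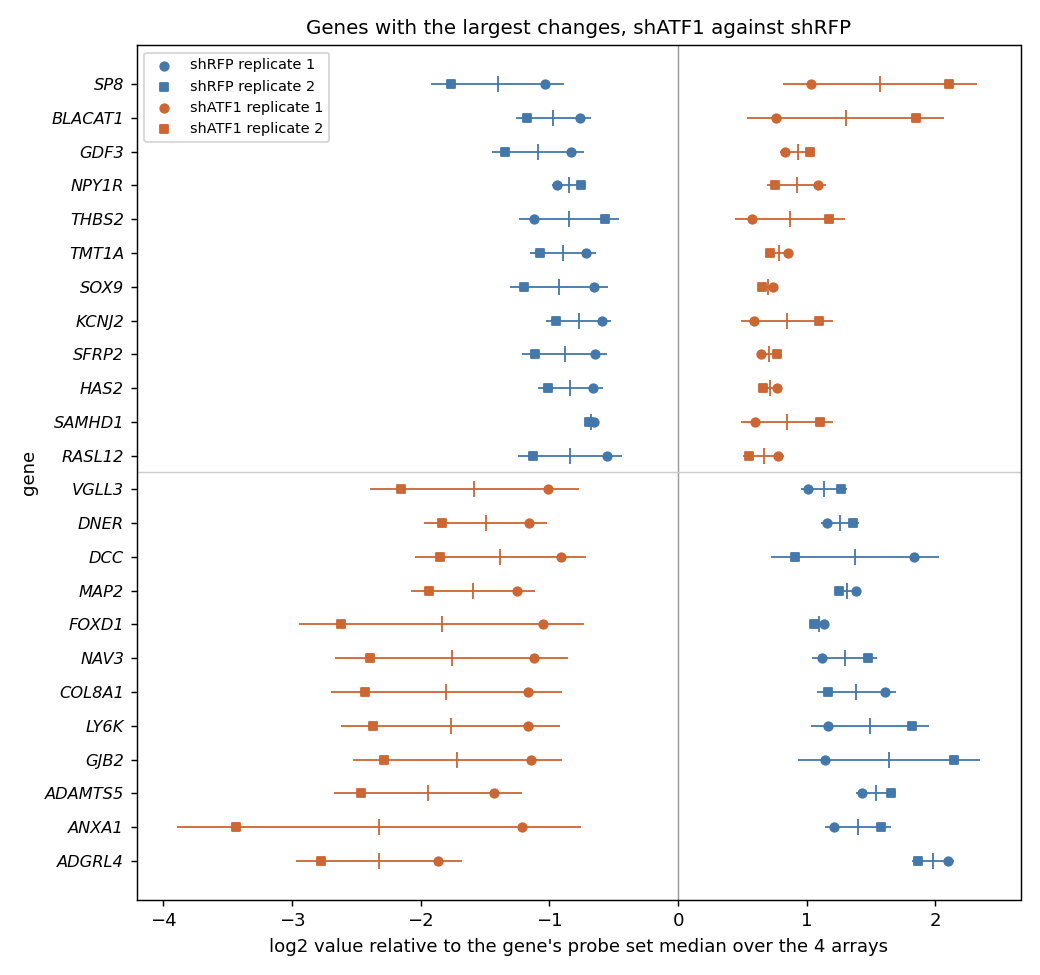
Centred log2 values (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per array, a tick at the group mean and bars of 1 SD (n = 2 per group). The shRFP and shATF1 arrays do not overlap in any of these genes, from SP8 with a difference of 2.97 to ADGRL4 with -4.31.

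In all, 257 genes were higher and 446 lower in shATF1 at an adjusted p under 0.05 (limma, Benjamini-Hochberg over 19775 genes), and 4473 had an unadjusted p under 0.05. A change of at least 1 on the log2 scale was found in 70 of the higher and 216 of the lower genes. In all 703 genes both shATF1 arrays lay on the same side of both shRFP arrays, and 54.7% of all genes showed such a separation, against 33.3% by chance. The count changed when single arrays were left out: without shRFP replicate 1, or without shRFP replicate 2, limma called 0 genes (3024 and 3548 at an unadjusted p under 0.05), without shATF1 replicate 2 it called 2 higher and 29 lower, and without shATF1 replicate 1 it called 350 higher and 888 lower. Each such fit has 1 residual degree of freedom, and the lone array is assumed to vary like the other group. All 703 genes kept their direction in each, as their separation requires, so direction cannot show whether the calls depend on 1 array. Of the 703, 567 lay farther from the shRFP mean in shATF1 replicate 2 than in replicate 1. Quantile normalization of the centred values raised the count to 536 higher and 984 lower. The mean of all probe sets of a gene, dimmer ones included, gave smaller changes for TMT1A (0.53), FGF4 (0.49), NEFM (0.42), ANXA1 (-2.35), LY6K (-1.87), COL8A1 (-1.23), NAV3 (-1.28), MAP2 (-1.73), DCC (-0.93), COL1A1 (-0.98), GATA3 (-0.59), PPARGC1A (-0.37) and GDF15 (-0.70). By that rule ANXA1, DCC, NEFM, GATA3, PPARGC1A, GDF15, EDNRB, FBN1 and VIM, 9 of the 56 named genes past the test, no longer passed.

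Of 26 measured genes of the primed pluripotency list, 6 were higher, 1 was lower and 19 did not pass, with a list median of 0.37 (camera, adjusted p = 0.000753). With an estimated correlation between genes this call was lost (adjusted p = 0.782), and fry gave an adjusted p = 0.169. Camera with an estimated correlation called a 26-gene list shifted by 0.4 in 0 of 20 simulated data sets. Its loss here therefore does not decide whether the list shifted. The correlation estimated for this list was 0.111, against the preset 0.01. The p-value at the preset correlation may therefore be too small. Adjusted over the list alone, 14 were higher and 2 lower, and 7 of the 26 differences were negative. Besides GDF3 and SFRP2, the higher genes were FGF4, NODAL, DNMT3B and PRDM14. The growth factor FGF4 rose by 1.00 ± 0.10. The ligand NODAL rose by 0.83 ± 0.14, the mean of 3 probe sets that disagreed, at 0.11, 1.16 and 1.22. DNMT3B, a de novo DNA methyltransferase, and PRDM14, a repressor of differentiation, rose by 0.65 ± 0.10 and 0.66 ± 0.10. The neuropeptide gene GAL fell by 1.19 ± 0.14. The core factors did not pass the test: NANOG differed by 0.38 ± 0.12 (SE, adjusted p = 0.148) and SOX2 by 0.14 ± 0.09 (SE, adjusted p = 0.436), with a 95% interval for SOX2 from -0.09 to 0.38. POU5F1 has no probe set here that names it alone and is not analysed here.

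Genes of DNA replication were the other group past the threshold. The correlation estimated for their list was 0.158, against the preset 0.01, so its p-value at the preset may also be too small. Of 20 genes of the G1/S and replication list, 2 were higher and 1 lower, with a median of 0.30 (camera, adjusted p = 0.000807, and adjusted p = 0.782 with an estimated correlation); 7 were higher and 1 lower adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, rose by 0.86 ± 0.10 and the cyclin CCNE2 by 0.88 ± 0.14, while the cyclin CCND1 fell by 0.82 ± 0.14. In the G2/M and mitosis list 2 of 20 genes were higher, the mitotic cyclin CCNB1 at 0.66 ± 0.12 and the ubiquitin-conjugating enzyme UBE2C at 0.63 ± 0.11; adjusted over the list alone, 2 were higher and 0 lower. That list had a median of 0.29 and missed the threshold (camera, adjusted p = 0.0791, and adjusted p = 0.782 with an estimated correlation). It passed without shRFP replicate 1 (camera, adjusted p = 0.00164) and without shATF1 replicate 2 (adjusted p = 0.0431), and not without shRFP replicate 2 (adjusted p = 0.582, median 0.13) or without shATF1 replicate 1 (adjusted p = 0.248). Quantile normalization (0.0362), the mean of all probe sets (0.0364) and level class 8 or above (0.0346) also brought its adjusted p under the threshold.

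Of the neuroectoderm and neural progenitor list, 1 of 32 measured genes was higher and 0 were lower, and 4 were higher and 1 lower adjusted over the list alone. The gene was OTX2, a homeobox factor of the anterior neural plate that stem cells also express, which rose by 0.65 ± 0.10 (SE, adjusted p = 0.0386). PAX6, a factor of early neuroectoderm, differed by 0.31 ± 0.12 (SE, adjusted p = 0.197, 95% interval 0.02 to 0.60) and SOX1 by 0.00 ± 0.11 (SE, adjusted p = 0.995), and neither passed. All 3 probe sets of SOX1 lay in level class 2 to 4, so its value does not show whether SOX1 responded. The list median was 0.10 (camera, adjusted p = 0.454), and 0.02 without shRFP replicate 2 (adjusted p = 0.582). Neuron genes moved both ways: DCX, a microtubule protein of migrating neurons, rose by 1.03 ± 0.11 and the neurofilament gene NEFM by 0.91 ± 0.15, while MAP2 and the synaptic gene SYT1 (-1.52 ± 0.24) fell. These were 2 higher and 2 lower of 20 genes, likewise adjusted over the list alone (camera, adjusted p = 0.876). In the neural crest list 2 of 14 genes were higher, SOX9 and the endothelin receptor EDNRB (0.63 ± 0.11), and 2 were higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.772). EDNRB rests on its brighter probe sets, and the probe set with the largest spread gave -0.96.

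Markers of the other germ layers and of extra-embryonic cells showed single falls. CER1, a secreted antagonist of Nodal and BMP made in early endoderm, fell by 1.40 ± 0.17 and was the 1 gene of 12 in the primitive streak and mesendoderm list past the test (camera, adjusted p = 0.644). AFP, the fetal plasma protein alpha-fetoprotein, fell by 1.68 ± 0.29 and was the 1 gene of 16 in the endoderm list (camera, adjusted p = 0.479). GATA3, a transcription factor of trophoblast, fell by 0.91 ± 0.14 and was the 1 gene of 19 in the trophoblast and amnion list (camera, adjusted p = 0.687). Adjusted over the list alone these lists held 1, 1 and 2 lower genes and 0 higher. None of 22 mesoderm genes passed by either count (camera, adjusted p = 0.876), the smallest p belonging to PDGFRA (0.71, adjusted p = 0.0781) and ACTC1 (-0.63, adjusted p = 0.0783). TBXT differed by 0.09 ± 0.10, SOX17 by 0.04 ± 0.10 and CDX2 by 0.14 ± 0.10, none of them past the test. Both SOX17 probe sets lay in level class 2 to 4, so its value does not show whether it responded.

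Stromal and mesenchymal transcripts were lower in part. In the fibroblast and stroma list COL1A1, the main chain of type I collagen, fell by 1.67 ± 0.30 and FBN1, the microfibril protein fibrillin, by 0.84 ± 0.13, 2 of 15 genes; 1 was higher and 7 lower adjusted over the list alone. The list median was -0.25 (camera, adjusted p = 0.0791, and adjusted p = 0.782 with an estimated correlation), and fry gave an adjusted p = 0.375. The list passed at level class 4 or above (adjusted p = 0.0174, median -0.70) and with quantile normalization (adjusted p = 0.0362), and with the mean of all probe sets the median was -0.05 (adjusted p = 0.0787). Without shATF1 replicate 1 the list passed the threshold (camera, adjusted p = 0.00184) with a median of -0.63, whereas without shATF1 replicate 2 the median was -0.10 (adjusted p = 0.1). Without shRFP replicate 1 or 2 it was -0.36 (adjusted p = 0.0519) and -0.18 (adjusted p = 0.209). Of its members not past the test, COL1A2 was at -1.56 (adjusted p = 0.107) and COL3A1, in level class 2 to 4, at 0.49 (adjusted p = 0.203). In the mesenchymal list VIM, the intermediate filament vimentin, fell by 0.84 ± 0.15, 1 of 12 genes, with 4 lower adjusted over the list alone (camera, adjusted p = 0.233). In the epithelial list GRHL2, a transcription factor of epithelial identity, rose by 1.30 ± 0.21, 1 of 13 genes, with 2 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.975).

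Stress genes were lower where they passed. Of 19 measured p53 targets 3 fell, namely GDF15, a secreted stress cytokine (-2.19 ± 0.36), ZMAT3, an RNA-binding protein (-1.46 ± 0.21), and GADD45A, a growth arrest gene (-1.05 ± 0.13); 1 was higher and 4 lower adjusted over the list alone. The list median was -0.13 (camera, adjusted p = 0.0791), and -0.03 without shRFP replicate 1 (adjusted p = 0.11), and CDKN1A and MDM2 stood at -0.13 and -0.27, not past the test. In the interferon list IFI6 fell by 1.31 ± 0.21, 1 of 25 genes, with 6 lower adjusted over the list alone (camera, adjusted p = 0.147, adjusted p = 0.025 without shATF1 replicate 2 and 0.11 to 0.442 without each other array). The interferon list passed with the mean of all probe sets (camera, adjusted p = 0.0435) and at level class 4 or above (adjusted p = 0.0267). In the main fit camera with an estimated correlation gave an adjusted p = 0.782, and fry gave 0.288. None of 22 genes of the unfolded protein and amino acid stress list passed, 2 being lower adjusted over the list alone (camera, adjusted p = 0.454). The smallest p in it belonged to ATF3 (-0.48, adjusted p = 0.0617) and HSPA5 (-0.51, adjusted p = 0.0672). None of 9 heat shock genes passed by either count (camera, adjusted p = 0.454), with HSPB1 at -0.46 and DNAJB1 at 0.40.

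Among signalling lists, Nodal/Activin targets had the largest median, 0.59, with GDF3, NODAL and the inhibitory SMAD7 (0.80 ± 0.14) higher and CER1 lower of 9 measured genes, and 5 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.16). Of the 9 differences 5 were positive and 4 negative, with a mean of 0.38. GDF3 and NODAL also belong to the primed pluripotency list. The Nodal/Activin list passed with the mean of all probe sets (camera, adjusted p = 0.0364) and with the probe set of largest spread (adjusted p = 0.0097, median 0.80). At level class 8 or above its median was 0.29 (adjusted p = 0.325). In the main fit camera with an estimated correlation gave an adjusted p = 0.782, and fry gave 0.175. Of 17 cAMP and CRE target genes FOS, an immediate early transcription factor, rose by 1.11 ± 0.11 and PPARGC1A, a coactivator of mitochondrial genes, fell by 0.67 ± 0.10, with 3 higher and 3 lower adjusted over the list alone (camera, adjusted p = 0.619). In the FGF/ERK feedback list DUSP4, a MAP kinase phosphatase, rose by 0.64 ± 0.10 while FOSL1 and PHLDA1 fell by 0.81 ± 0.12 and 0.60 ± 0.11, 3 of 14 genes, with 7 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.573). SMAD7 was higher and GATA3 lower among 14 BMP targets (camera, adjusted p = 0.982), with 2 higher and 1 lower adjusted over the list alone. HEY2 rose by 0.87 ± 0.12, the 1 gene of 13 Notch targets (camera, adjusted p = 0.552), with 1 higher and 1 lower adjusted over the list alone. None of 13 WNT targets passed by either count (camera, adjusted p = 0.43), with DKK1 at 0.37 and LGR5 at 0.29, the latter in level class 2 to 4 and so not told from background.

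Metabolic and ribosomal genes showed 1 call. ADM, the peptide hormone adrenomedullin, fell by 0.78 ± 0.12, 1 of 24 genes of the glycolysis and hypoxia list, with 1 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.975). None of 16 cholesterol synthesis genes passed (camera, adjusted p = 0.734), with INSIG1 at 0.63 and DHCR7 at 0.48, and 2 were higher and 1 lower adjusted over the list alone. None of 21 oxidative phosphorylation genes (camera, adjusted p = 0.906) and none of 19 cytosolic ribosomal protein genes (camera, adjusted p = 0.454) passed by either count. The values of smallest p were -0.56 for NDUFS4 and -0.41 for CYCS, whose probe set with the largest spread gave 0.85, and -0.13 for RPS9 and -0.08 for RPLP1.

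**Figure D2:**
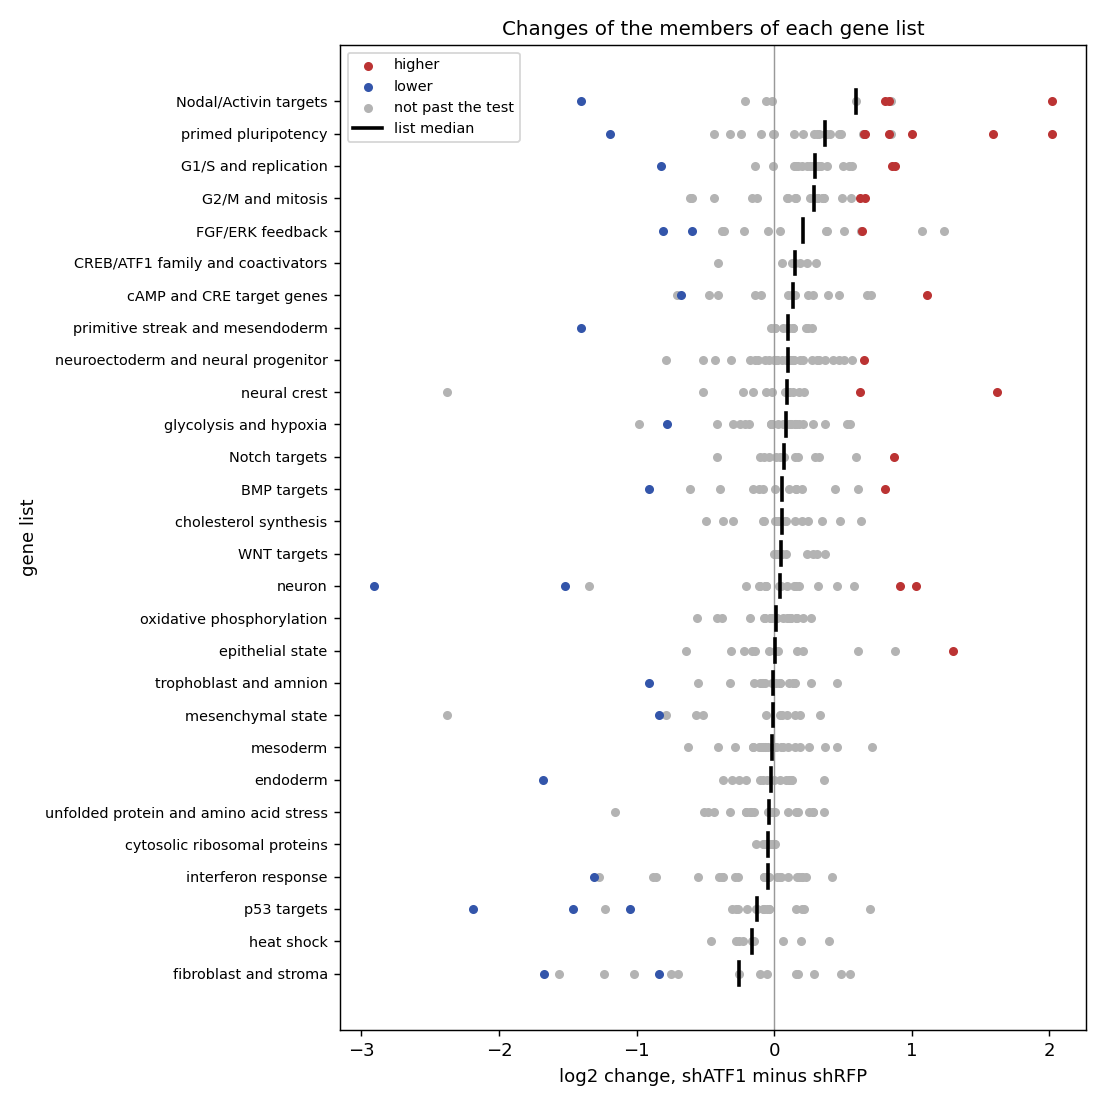
Log2 change, shATF1 minus shRFP, of each measured member of the 28 gene lists (1 point per gene, red for higher, blue for lower and grey for not past the test), with a bar at the list median. Medians run from -0.25 for fibroblast and stroma to 0.59 for Nodal/Activin targets, and the primed pluripotency list holds 6 red points and 1 blue point.

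Of the 28 lists, 2 passed with camera's preset correlation and 7 had an unadjusted p under 0.05. With an estimated correlation 0 passed (camera, the smallest adjusted p = 0.782), and with fry 0 (the smallest adjusted p = 0.169). Because the estimated correlation called the simulated shifted list in 0 of 20 data sets, its result decides for none of the lists. When the arrays were split so that both groups held a shATF1 and a shRFP array, up to 2 lists passed as well. The count of 2, primed pluripotency and G1/S, is therefore no support by itself for an effect of the hairpin. The median and the mean of the members had opposite signs in the neuron, neural crest, primitive streak, mesoderm, glycolysis and oxidative phosphorylation lists, and camera's direction followed the median except in the last.

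Both shATF1 arrays moved away from shRFP in the same direction. Across genes, which are not independent replicates, the difference of the arrays numbered 1 correlated with that of the arrays numbered 2 at r = 0.667, and at 0.704 with the shRFP arrays exchanged. The SD over genes of the difference from the shRFP mean was 0.311 for shATF1 replicate 1 and 0.428 for replicate 2, and 567 of the 703 called genes lay farther from the shRFP mean in replicate 2. With 1 array per clone number, hairpins were not tested against each other. Arrays of one group differed by a median absolute difference of 0.12 (shRFP) and 0.127 (shATF1) over genes, with 0 identical probe sets.

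Signs of RNA quality did not separate the groups. The log2 difference of the 3' and 5' control probe sets of GAPDH, relative to their own medians, was 0.14 and -0.0139 in the shRFP arrays and 0.0131 and 0.00991 in the shATF1 arrays. For ACTB it was 0.0957 and -0.0776 in shRFP and 0.0782 and -0.0782 in shATF1. The SD of all centred values was 0.224 and 0.199 in shRFP and 0.158 and 0.267 in shATF1, each pair in the order of the replicate numbers.

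Human embryonic stem cell cultures can gain chromosome parts, and the genes of each chromosome were therefore compared. None of 23 chromosomes passed (camera, smallest adjusted p = 0.199). Chromosomes 16, 17, 19, 20 and 22 had an unadjusted p under 0.05 with medians of 0.07, 0.07, 0.08, 0.07 and 0.08, against 0.03 over all genes. Their genes were short, with median lengths from 14675.5 bp (chromosome 19) to 20311.5 bp (chromosome 20), against 42693 bp on chromosome 4. Chromosome 11, at 17746 bp, had a median of 0.04. A gain was not told apart from the trend with gene length described below. Without shATF1 replicate 1, chromosome 19 passed (camera, adjusted p = 0.038). Runs of 25 neighbouring genes did shift: the strongest, from LRRC8B to F3 on chromosome 1, had a median of -0.53, and 0 of 1000 shuffled gene orders held a run as large. Of its 25 genes 19 lay below 0. The order of genes came from the GRCh38.p14 assembly, which served only for names, lengths and neighbours.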

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

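Chosen only after seeing the data were the alternative fits by level class and with a length trend removed. The main fit's probe set rule, its missing intensity trend and the level floor for the largest changes also departed from the plan, because the values proved to be centred. Against 257 higher and 446 lower genes, a replicate block gave 62 and 248, quantile normalization 536 and 984, and testing all probe sets 142 and 332. A log2 change of at least 1 as well gave 70 and 216, and Student's t-test 1 and 0 (2541 at an unadjusted p under 0.05). Genes of level class 8 or above gave 247 and 264, where fewer genes were tested. The dimmest array sets a gene's class, so this filter leaves out genes that fell below 8 in shATF1 and genes that rose from below 8 in shRFP. Of the called genes in class 4 to 8, 112 were higher and 252 lower. Of the called genes, 36.6% were higher in the main fit and 48.3% with this filter. Leaving out single arrays gave 0 to 350 higher and 0 to 888 lower, with 1 array left in a group and assumed to vary like the other. Of the 703 called genes, 246 stayed past the threshold with the replicate block, 698 with quantile normalization and 685 with the length trend removed. The labels do not say what the replicate numbers mark, and the arrays were treated as unpaired: deviations of same-numbered arrays correlated at -0.0224 over genes, but the medians of gene runs at 0.362, so a shared day or culture stays open. Quantile normalization acts on centred values here and so evens out deviations, not levels. The number of gene lists past the threshold, 2, became 4 with quantile normalization, 5 with the mean of all probe sets, 4 at level class 4 or above, 0 with an estimated correlation and 0 with fry, and 2 to 4 without single arrays. Primed pluripotency and G1/S were among them in every setting that called any list. The number of chromosomes past the threshold, 0, became 1 (chromosome 17) at level class 8 or above and 0 to 1 without single arrays, chromosome 19 passing without shATF1 replicate 1. Replicate agreement, 0.667, was 0.64 after quantile normalization and 0.661 with the length trend removed. With the probe set of largest spread EDNRB turned to -0.959 and CYCS to 0.854, because another probe set was taken. Other named genes and lists past the test in either setting kept their direction. The cause of the other changes was not tested. The ATF1 level has no value under any setting, replicate agreement cannot be had without an array, and the planned trend, dim filters and pseudocounts were not run because the values are centred logs. Signal over background is unknown, so dim genes cannot be told from absent ones.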

Other observations

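The tests in this part were chosen only after the results were seen, except that of the length trend among genes not past the threshold, and those on gradients and on the chromosome run replaced earlier forms whose values are printed too. Genes that share the letters of their symbol were grouped into 224 families of at least 10. Of these, 6 passed with camera's preset correlation, 3 of them with lower and 3 with higher values in shATF1, and 0 passed with an estimated one. The estimated correlation also called the simulated shifted list in 0 of 20 data sets, so its values below do not decide. Of 43 collagen genes 10 were lower and 0 higher, with a median of -0.22 (camera, adjusted p = 0.000227, and adjusted p = 0.969 with an estimated correlation). Besides COL8A1 and COL1A1 they included COL7A1, the anchoring fibril collagen of skin (-2.44 ± 0.35), COL23A1 (-1.23 ± 0.16) and the basement membrane chains COL4A2 (-0.88 ± 0.14) and COL4A6 (-0.89 ± 0.15). With the length trend removed 5 families passed, and the collagens kept a median of -0.21 (camera, adjusted p = 0.0087). The 5 included RPL genes (median -0.10, adjusted p = 0.0087) and UBE genes (median 0.15, adjusted p = 0.0337). Both had missed the threshold without that correction (camera, adjusted p = 0.0921 and 0.0756).

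GALNT genes, which start mucin-type O-glycosylation, had 4 of 17 members lower and 0 higher, GALNT7 at -1.29 ± 0.14 and GALNT3 at -1.14 ± 0.15 among them (camera, adjusted p = 0.00728, and adjusted p = 0.969 with an estimated correlation). Integrin alpha chains had 2 of 12 lower, ITGA3 at -1.21 ± 0.15 and ITGA1, in level class 2 to 4, at -0.80 ± 0.10 (camera, adjusted p = 0.0464, adjusted p = 0.969 with an estimated correlation and 0.0588 with the length trend removed). RGS genes, which switch off G protein signalling, had 4 of 22 lower, led by RGS5 at -1.44 ± 0.11 and RGS17 at -1.41 ± 0.15, and as a family missed the threshold (camera, adjusted p = 0.0534). The families with higher values had 0 genes past the test: KDM histone demethylases (18 genes, median 0.22, camera, adjusted p = 0.0464), genes whose symbols start with TP (11 genes, median 0.29, adjusted p = 0.0464) and beta protocadherins (15 genes, median 0.25, adjusted p = 0.049). With an estimated correlation each had an adjusted p = 0.969, and with the length trend removed 0.0087 for KDM, 0.0588 for TP and 0.0979 for the protocadherins. The medians of these families kept their sign after quantile normalization and median centring.

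The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 703 genes, and 1 of the 3 splits reached that count. The highest count of the other splits was 0 genes (limma), with 155 at an unadjusted p under 0.05 in the split that joins the arrays numbered 1. Each other split puts a shATF1 and a shRFP array into both groups. Any difference between shATF1 and shRFP then adds to the spread within groups and lowers the count. The 0 is therefore no support for the 703 calls. For gene lists the highest of the other splits was 2, as many as in the real split.

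Beside the shift of the primed pluripotency list, COL1A1, FBN1 and VIM were lower, while the fibroblast and mesenchymal lists missed the threshold (camera, adjusted p = 0.0791 and 0.233). A smaller share of cells that are not pluripotent is a candidate explanation for the shift. It would raise genes found only in pluripotent cells by 1 common factor. Of the 26 members, 13 had 95% intervals that left out the list median, 7 above and 6 below it, and 3 lay wholly below 0. Because other cells may also express some members, which would blunt their rise, this spread does not decide, and a change of composition cannot be told apart from a change within cells or an effect of the ATF1 hairpin.

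Long genes were lower in shATF1: the rank correlation of change with gene length was -0.159 over 13813 protein-coding genes, and the share of genes called lower was 1.95% in the shortest length decile and 6.37% in the longest, with 0.941% and 1.88% called higher. Among genes with an unadjusted p of 0.05 or more it was -0.109, so the called genes alone do not account for it. A gradient between arrays apart from the hairpin may contribute, since the shRFP arrays, replicate 2 minus 1, had a correlation of -0.068 with length and the shATF1 arrays -0.189. The shATF1 value is also what a stronger effect in replicate 2 would give, and a gradient and the hairpin cannot be told apart here because the shRFP value is neither close to nor far below the one between groups. RNA degradation, which would raise the 3' minus 5' difference, was not settled. From shATF1 replicate 1 to 2 that difference changed by -0.0032 for GAPDH and by -0.156 for ACTB. Between the shRFP arrays it went from 0.14 to -0.0139 for GAPDH and from 0.0957 to -0.0776 for ACTB. These controls show no added degradation in either replicate 2, but 2 transcripts do not decide for all genes.

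Runs of neighbouring genes shifted on 8 chromosomes, with 113 overlapping runs below and 0 above the range of 95% of shuffled orders. A lost part of chromosome 1 would lower the abundant genes of the LRRC8B to F3 run together. Of its 15 genes in level class 8 to 16, 8 had 95% intervals above the run median of -0.526, so these genes did not all fall by that amount. The class leaves out genes that fell below 8 in shATF1, and the run was picked as the largest, so this does not decide on a loss. The earlier form of this test, the size of the run alone, had been met, since 0 of 1000 shuffled orders reached it. A gradient between arrays apart from the hairpin is consistent with another value: over 599 separate runs, the medians of shATF1 replicate 2 minus 1 and of shRFP replicate 2 minus 1, which share no array, correlated at 0.362, against -0.0236 over single genes. Run medians between the groups correlated, by rank, at -0.596 with gene length. A hairpin effect on regions of long genes stays open and untested.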
